A study of Caenorhabditis elegans with 4 samples.

How the data were processed

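ChIP-seq of EFL-1 was performed on L1 larvae of the lin-35(n745) strain MT10430. The 4 samples fall into 2 groups by their titles, EFL-1 ChIP (2 samples) and input (2 samples). Per the labels' protocols, synchronized worms were fed E. coli HB101 and grown at 20 °C, fixed in 2% formaldehyde, which was then quenched in Tris (100 mM), and sonicated, and 10% of the lysate was kept as input. The stage label carries the tag 26dC beside a stated growth temperature of 20 °C, and this difference could not be settled. The sample descriptions name a rabbit polyclonal EFL-1 antibody, while the general protocol text describes antibodies against GFP and RNA polymerase II; the descriptions were followed. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. Replicates are numbered 1 and 2 as in the sample titles, although the deposited files of these samples carry the numbers 2 and 3.

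The deposited data are peak lists in WormBase WS220 coordinates, per the file headers. The source field of each line, per the file headers and lines, names SPP and IDR, that is, a peak caller and the irreproducible discovery rate procedure that keeps peaks ranked alike in replicates. Versions, thresholds, the aligner, the use made of each input and the way in which the replicates were combined are not given in the sources used here. Each line holds a score that the authors deposited without a stated unit. It was used only to rank peaks within a list. In both replicate lists the score never rose with the number in the peak's name by more than 8.68e-05 (replicate 1) or 0.000114 (replicate 2). The number was therefore taken as the authors' rank. Among the 5002 replicate 1 and 3810 replicate 2 peaks tied at the top score, the scores cannot check this order. Within such ties, and in the combined list, "strongest" means lowest in number. In the combined list the score was the same in every peak, and the number was used there too; this choice was made after the scores were seen. Most weak peaks had 1 fixed width, 324 bp in replicate 1 (91.4% of peaks) and 330 bp in replicate 2 (93.7%), and 52.8% of combined peaks also had 330 bp, so that widths of such peaks are settings of the caller rather than measurements. The combined list repeated 9 intervals exactly, and 54 of its peaks overlapped the previous one; all were kept as deposited.

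Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Peaks counted as shared when they overlapped by at least 1 bp. Chance overlap was measured by rotating one list by a random step along each chromosome 1000 times, with a one-sided permutation p. Rank agreement was Spearman's rho and Pearson's r over peaks that overlapped one to one, with 100000 permutations. Chromosome counts were compared with each chromosome's share of the nuclear extent (100.2 Mb), the extent being the highest peak end in any list, by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 6 chromosomes. Intervals are exact (Clopper-Pearson) 95% intervals over peaks and cover counting error only. The overlap and chromosome tests were first tested on simulated lists of 4966 peaks. Of a simulated shared share of 60%, 61.2% was found with 2.93% after rotation. A simulated X ratio of 0.55 was found as 0.56 (0.52 to 0.61). The simulated peaks were placed evenly at random and independently, and were fewer than in the replicate lists. How the tests behave on longer lists or on unevenly spread peaks was therefore not simulated.

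With the exceptions given below, the tests, 15 gene lists, the alternatives and the rule for named sites were fixed before the data were examined. That rule named genes by their peaks or, with no usable annotation, the 10 highest-scoring combined peaks by position; as scores were tied, the peak number decided. The gene table at hand was of assembly WBcel235, not WS220, and builds were not mixed. For that reason the gene lists, distances to gene starts, sequence motifs and the planned comparison with gene starts per chromosome were not analysed here, and chromosome extent, planned as the alternative denominator, was used. The plan set the binomial test for X and Fisher's exact test per chromosome. The binomial test was instead run on all 6 chromosomes. Alternatives tried were a reciprocal overlap of 50%, centres within 200 bp, the stronger 50% of each list, each replicate alone, and, added after the data were seen, the strongest peaks alone, nuclear peaks alone, merged peaks, the weaker 50% of the combined list and 500 kb bins. Mitochondrial peaks entered the replicate overlap but not the chromosome comparison. The input samples themselves were not analysed here.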

Results

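Binding of EFL-1 was mapped in larvae that carried the lin-35(n745) mutation. EFL-1 is an E2F-family transcription factor of Caenorhabditis elegans, and LIN-35 is the worm homologue of the retinoblastoma tumour suppressor protein, with which E2F factors act in a repressor complex. The strain was MT10430, the animals were hermaphrodites at the first larval stage (L1), and 1 genotype, 1 stage and 1 antibody were studied. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with a rabbit antibody against EFL-1 gave 2 ChIP samples, each with an input sample of total chromatin DNA taken from the same lysate. A peak list was analysed for each ChIP replicate, together with 1 list that combined them. The design implies a comparison of the replicates with each other, of the combined list with each replicate, and of the chromosomes with each other. Whether loss of LIN-35 changed EFL-1 binding was not addressed by these samples, because no animals with intact lin-35 were among them.

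The combined list held 4966 EFL-1 ChIP peaks on the nuclear chromosomes, or 4912 after overlapping peaks were merged. Combined peaks are also called sites here, although binding of EFL-1 at them was not tested separately. Replicate 1 had 22275 peaks and replicate 2 had 22464 peaks. Combined peaks had a median width of 330 bp, ranged from 82 to 884 bp, and together covered 1.38 Mb, or 1.37% of the nuclear genome as far as peaks extended. The median is a fixed width set by the caller, which 2621 of the 4966 combined peaks (52.8%) had exactly, and the covered length depends on it too. The longer replicate lists covered 6.88 Mb (6.87%) and 7.12 Mb (7.11%). All 4966 combined peaks carried the same score, 4.001, whereas scores in the replicate lists ran from 0.00435 to a shared top value, which was 4.0001 for 5002 peaks of replicate 1 and 3.88 for 3810 peaks of replicate 2. Read depth per sample was unknown, since the peak lists give neither read counts nor enrichment folds, so no interval on the strength of a single site could be given.

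The 10 strongest combined sites, by the authors' peak number, lay on 4 autosomes. Chromosome II held 5 of them, chromosomes III and IV held 2 each, chromosome V held 1, and chromosomes I and X held none. In WS220 coordinates the strongest site was on chromosome II from 216540 to 217002, and it was peak 2 in replicate 1 and peak 1 in replicate 2. The next was on chromosome II from 14383551 to 14383976 (peak 1 in replicate 1, peak 4 in replicate 2). It was followed by chromosome IV from 12724574 to 12725044 (peaks 6 and 3) and chromosome III from 10758931 to 10759391 (peaks 14 and 2). The fifth lay on chromosome II from 10563313 to 10563720 (peaks 10 and 5) and the sixth on chromosome III from 13256334 to 13256759 (peaks 7 and 6). The other four were on chromosome II from 4739951 to 4740380 (peaks 4 and 12), chromosome V from 5939494 to 5939911 (peaks 17 and 8), chromosome II from 15010369 to 15010766 (peaks 20 and 9) and chromosome IV from 15570713 to 15571125 (peaks 18 and 7). Each of the 10 sites was therefore among the 20 strongest peaks of replicate 1 and the 12 strongest of replicate 2. Their widths, from 398 to 471 bp, were all above the fixed width of 330 bp. The genes at these sites were not analysed here.

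Strong EFL-1 ChIP peaks recurred in both replicates, and weak ones often did not. All 1000 of the strongest peaks of replicate 1 overlapped a peak of replicate 2, and all 1000 of the strongest peaks of replicate 2 overlapped a peak of replicate 1. Among peaks 4001 to 5000 the shares were 91.0% and 90.2%, and among peaks 9001 to 10000 they were 42.6% and 43.3%. Over the full lists, 11239 of the 22275 replicate 1 peaks were found in replicate 2 (50.5%, exact 95% interval 49.8 to 51.1%). Conversely, 11214 of the 22464 replicate 2 peaks were found in replicate 1 (49.9%, 49.3 to 50.6%). When the replicate 2 list was rotated at random along each chromosome, the mean overlap was 14.04% for replicate 1 peaks and the highest of 1000 rotations was 15.9% (one-sided permutation p = 0.001, the smallest these rotations can give). Even at peaks 20001 to 21000, 23.9% of replicate 1 peaks had a partner, against 13.99% after rotation. Rotation breaks any alignment that both lists share, whatever its source. An excess over it therefore does not show that the shared peaks are sites of EFL-1 binding.

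**Figure D1:**
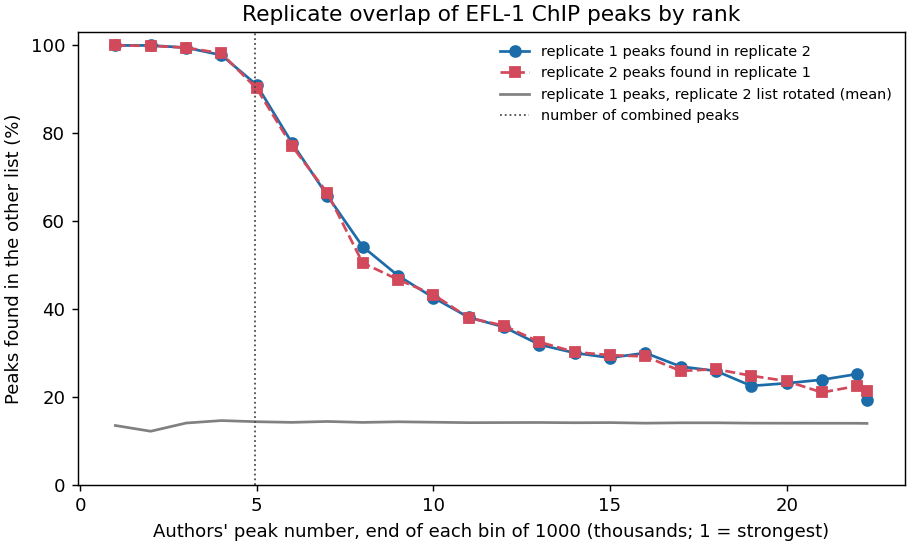
Share of peaks (%) of each EFL-1 ChIP replicate that overlapped a peak of the other by at least 1 bp, in bins of 1000 peaks from the strongest to the weakest; the grey line is the mean share for replicate 1 after 1000 rotations and the dotted vertical line marks 4966 peaks. Both curves start at 100%, pass 91.0% and 90.2% at peaks 4001 to 5000, and stay above the grey line, which has a mean of 14.04%.

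Restricted to as many of the strongest peaks as the combined list holds, 4170 of 4966 replicate 1 peaks (84.0%) overlapped one of the 4966 strongest of replicate 2, against 3.33% after rotation. The converse share was 4179 of 4966 (84.2%), with one-sided permutation p = 0.001 for both. Of these strongest peaks, 111 in replicate 1 (2.24%) and 2.40% in replicate 2 overlapped no peak of any rank in the other list. The first such peak was number 2256 in replicate 1 and number 1110 in replicate 2. Over 9450 peaks that overlapped one to one, the scores of both replicates were correlated across peaks, which are not independent replicates (Spearman rho = 0.78, Pearson r of log10 scores = 0.61, permutation p = 1e-05 for each, the smallest 100000 resamples can give). Both scores were at their top value in 34.8% of these pairs. By peak number, which has no ties, rho was 0.84.

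Nearly every combined site was present in both replicates. Of the 4966 combined peaks, 4962 overlapped a replicate 1 peak (99.9%, exact 95% interval 99.8 to 99.98%) and 4951 a replicate 2 peak (99.7%, 99.5 to 99.8%), which left 4 and 15 without a partner. Both replicates held 4947 of them (99.6%). Their median peak number was 2468 in replicate 1 and 2463 in replicate 2, so that the combined sites came from the strongest part of each list. Peaks among the 4966 strongest of both replicates accounted for 4141 combined sites (83.4%). The number of a peak in the combined list followed its number in replicate 1 (Spearman rho = 0.97 across peaks) and in replicate 2 (rho = 0.95). These values are not independent, because the combined list rests on the same samples. Its lines also name the IDR procedure, which keeps peaks ranked alike in replicates. High shares and ranks in both replicates follow from such a selection, so they are no separate evidence of reproducibility.

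Combined EFL-1 ChIP peaks were unevenly spread over the chromosomes, densest on III and I and sparsest on X and V. Chromosome III held 989 combined peaks, or 71.8 per Mb, which was 1.45 times the number expected from its length (exact 95% interval 1.37 to 1.53). Chromosome I held 975 peaks (64.8 per Mb, ratio 1.31, 1.23 to 1.38). At the other end, chromosome X held 589 peaks where 878 were expected (33.2 per Mb, ratio 0.67, 0.62 to 0.72), and chromosome V, the longest, held 735 where 1037 were expected (35.1 per Mb, ratio 0.71, 0.66 to 0.76). Chromosome II was slightly above expectation with 831 peaks (ratio 1.098, 1.03 to 1.17), and chromosome IV had 847 peaks (ratio 0.98, 0.92 to 1.04).

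In two-sided exact binomial tests with Benjamini-Hochberg adjustment over the 6 chromosomes, III (adjusted p = 3.45e-32), X (5.55e-29), V (1.23e-27), I (2.53e-18) and II (0.00444) differed from expectation, and IV did not pass the test (0.477). Neighbouring peaks are not independent, so 500 kb bins were also compared by permutation. The permutation treats bins as independent, although neighbouring bins often held alike counts, so its p-values may be too small. X averaged 16.7 ± 4.41 combined peaks per bin (SD, n = 35 bins) against 26.4 ± 10.5 elsewhere (SD, n = 162 bins), with adjusted permutation p = 2e-05. Chromosome III averaged 35.9 ± 9.48 (SD, n = 27 bins; adjusted permutation p = 2e-05), chromosome I 32.3 ± 8.82 (SD, n = 30 bins; 3e-05) and chromosome V 17.4 ± 6.90 (SD, n = 41 bins; 2e-05). For chromosome II, at 27.1 ± 9.47 (SD, n = 30 bins), the call was lost over bins (adjusted permutation p = 0.208).

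**Figure D2:**
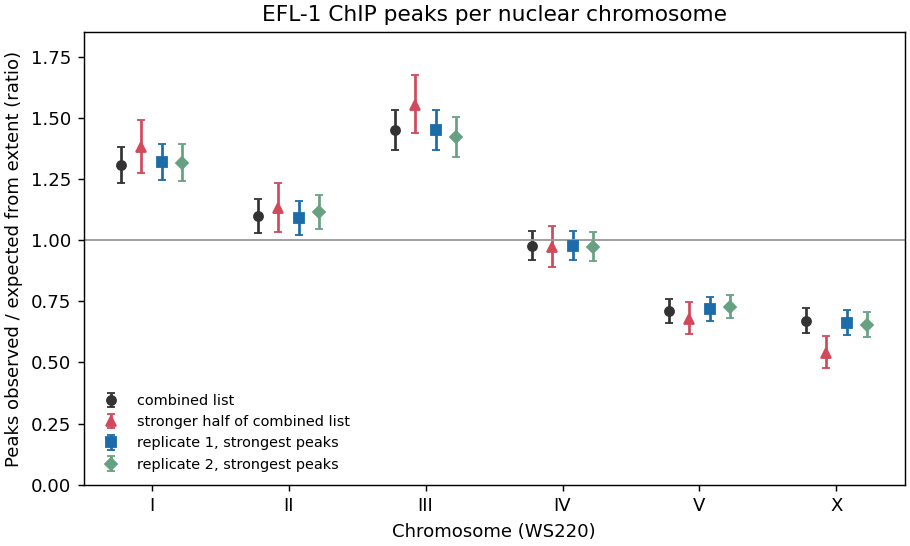
Observed over expected number of EFL-1 ChIP peaks (ratio, linear axis) on each nuclear chromosome for the combined list, its 2483 strongest peaks (the stronger part), and the strongest 4966 peaks of each replicate less those on mitochondrial DNA; bars are exact 95% intervals over peaks and the line at 1 is the number expected from chromosome extent. III and I lie above 1 and V and X below it in each of the 4 sets, which share most of their peaks. X falls from 0.67 in the combined list to 0.54 in its stronger part.

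Each replicate alone gave the same order of the extremes as the combined list. That list rests on the same samples, however. Of its 4966 sites, 4141 (83.4%) were among the 4966 strongest peaks of both replicates. Similar ratios in the combined list and in each replicate are therefore no separate evidence for the uneven spread. Among its strongest peaks, the X ratio was 0.66 in replicate 1 (578 of 4947 nuclear peaks) and 0.65 in replicate 2 (571 of 4942). For chromosome III the ratios were 1.45 (986 peaks) and 1.42 (965 peaks), for chromosome I both were 1.32, and for chromosome V they were 0.72 and 0.73. Among the 2483 strongest combined peaks, X held 237 (ratio 0.54, exact 95% interval 0.48 to 0.61) and III held 530 (ratio 1.55, 1.44 to 1.67). Among the other 2483, X held 352 (ratio 0.80, 0.73 to 0.88) and III held 459 (ratio 1.34, 1.23 to 1.46).

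**Figure D3:**
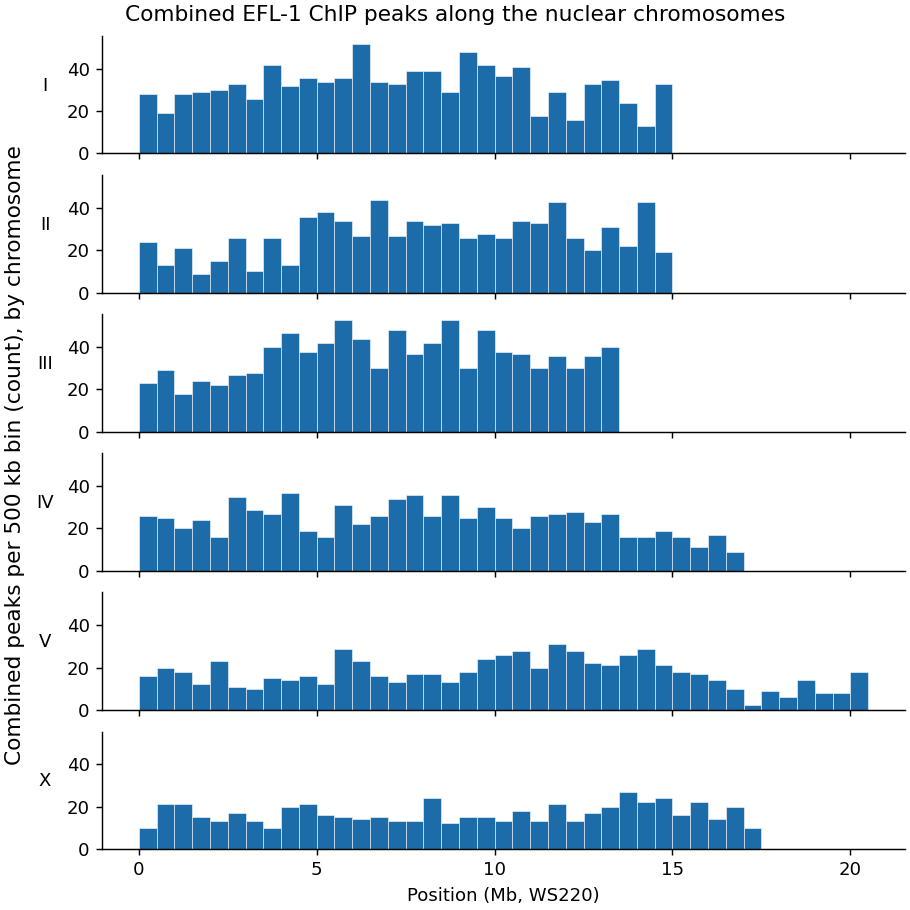
Number of combined EFL-1 ChIP peaks in consecutive 500 kb bins along the 6 nuclear chromosomes (position in Mb, WS220). Bins on chromosome III average 35.9 peaks and those on chromosome X 16.7.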

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

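The comparison with nuclear peaks and the tally of widths were chosen after the mitochondrial peaks had been seen; the rotation test of their positions was set before its result was known.

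Mitochondrial DNA carried peaks in both replicate lists, 23 in replicate 1 and 26 in replicate 2, in data that the nuclear comparisons do not use. These are numbers of peaks, and no read signal was measured. In replicate 1, 19 of the 23 had the top score and the strongest was peak 612. In replicate 2, 23 of the 26 had the top score and the strongest was peak 338. They covered 52.4% and 56.0% of the mitochondrial extent, and the combined list held 0 of them.

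Removal of mitochondrial peaks when the lists were combined may account for that absence: 1991 of 1991 nuclear peaks that ranked as high in both replicates (100%) were in the combined list, against 0 of 10 mitochondrial ones, although no source states such a step. Coverage with no preferred positions is argued against, since 16 of the 23 replicate 1 centres lay within 50 bp of a replicate 2 centre, against 4.53 on average after rotation (one-sided permutation p = 0.00314). All 23 and all 26 had the fixed width of their list, a setting of the caller that measures no shape, against 40.98% and 38.03% of nuclear peaks between the strongest and the median mitochondrial rank. The ranges are unlike, because mitochondrial peaks ran down to numbers 11457 and 20714. Over the full lists, 91.4% and 93.7% of peaks had the fixed width. A reproducible difference in mitochondrial coverage between ChIP and input, unrelated to EFL-1, stays open, because read depths were not at hand. No biological explanation was tested.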

How the results depend on the processing

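The strongest 4966 peaks alone, nuclear peaks alone, merged peaks, the weaker 50% of the combined list and 500 kb bins were chosen after the data were seen. Replicate overlap, rank agreement and the chromosome calls for I, III, V and X kept direction and side of the threshold under each alternative run. IV stayed uncalled. Of the alternative values, 49 counted as unmoved, 5 moved and 3 lost a call. These labels followed unlike rules. A tested value counted as unmoved while it kept its side of the threshold. A share of combined peaks, which had no test, counted as moved when it left the exact interval of the main value. Replicate 1 overlap going from 50.5% to 40.3% or 84.0% thus counted as unmoved. Combined peaks found in replicate 2, going from 99.7% to 99.4%, counted as moved. The tally therefore does not measure how far values shifted. The overlap share of replicate 1 peaks ranged from 40.3% (reciprocal 50% overlap) to 84.0% (the strongest 4966 peaks), with p = 0.001 in the rotation permutation throughout, and the X ratio from 0.54 (the 2483 strongest combined peaks) to 0.84 (peaks within 10 kb counted once, which draws ratios towards 1 by construction). Under a reciprocal 50% overlap, the combined peaks found fell to 91.8% in replicate 1 and 84.8% in replicate 2; with centres within 200 bp the replicate 2 share was 99.4%, and between the stronger 50% of each list it was 100% in both replicates. The cause was not tested. The excess on chromosome II lost its call in the weaker 50% of the list (ratio 1.07), with peaks within 10 kb counted once (1.05) and over 500 kb bins (27.1 peaks per bin, adjusted permutation p = 0.208). The combined list was not remade without a replicate. The strongest 4966 peaks of each replicate's own list gave X ratios of 0.65 to 0.66. They are largely the same peaks as the combined list, so these ratios are no separate evidence. The overlap results need both replicates. No paired analysis was possible because the input samples that share the replicate numbers were not analysed here and no result compares 2 groups of samples. The comparisons with gene starts, gene lists, motifs and scores at gene lists were not run, nor were their alternatives, for want of a matching annotation. Without read depths, whether a weak peak of 1 replicate was absent from the other or missed there is open.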

Other observations

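The odds ratios by rank, the ratios of stronger and weaker peaks, the random placements before merging, the central-position test and the counts of windows were chosen after the results had been seen; the permutation of 500 kb bins was fixed before its value was known.

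The deficit of EFL-1 ChIP peaks on X was steepest at the strongest peaks and shrank step by step down the combined list. X held 67 of the first 1000 peaks, a ratio of 0.38 to the number expected, then 105 (0.59), 129 (0.73), 142 (0.80) and 146 of the last 966 (0.86). Chromosome III went the other way at the top, with a ratio of 1.73 over the first 1000 peaks, 1.31 over peaks 2001 to 3000, 1.26 over peaks 3001 to 4000 and 1.45 over the last 966. Chromosome V stayed between 0.68 and 0.75 in every one of these bins. In the replicate lists the X ratio was also lowest over the first 1000 peaks (0.37 in replicate 1, 0.36 in replicate 2), but the steps were less regular. From peaks 3001 to 4000 to peaks 4001 to 5000 it went from 0.80 to 0.79 in replicate 1 and from 0.88 to 0.66 in replicate 2.

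For the deficit on X, the tests argue against clustering within single 500 kb bins as the whole cause. For its change with rank, they argue against the ranking of 1 library. As the whole cause, clustering of peaks within single 500 kb bins is argued against by the permutation of these bins between X and the other chromosomes (p = 1e-05, the smallest 100000 resamples can give). That permutation treats bins as independent, so its p may be too small, and it does not reach clustering over wider regions. Counting peaks within 10 kb once moved the X ratio from 0.67 to 0.84, but such merging removes more peaks where they are dense, and 100 random placements of as many peaks per chromosome gave 0.82 on average (0.78 to 0.86) after it, so this shift decides nothing. The odds of lying on X for the 1000 strongest combined peaks were 0.47 times those of the other 3966 (exact 95% interval 0.36 to 0.62). Against all other nuclear peaks of the longer replicate lists, the odds ratio was 0.40 (0.31 to 0.51, 21254 others) in replicate 1. In replicate 2 it was 0.37 (0.28 to 0.48, 21442 others). As the source of this difference by rank, the ranking of 1 library is argued against because both replicate intervals lay below 1. These odds ratios compare ranks within a list, so they cannot speak to the deficit against length or to a cause shared by both libraries. The sizes of the replicate odds ratios are not comparable with the combined value. A lower number of possible sites on X stays open. Alone, and if peaks of every rank were alike in kind, it would give the stronger and the weaker 2483 combined peaks overlapping ratios. They did not have these (0.54, 0.48 to 0.61, against 0.80, 0.73 to 0.88). All other chromosomes also moved towards 1 in the weaker peaks, III from 1.55 to 1.34, so this difference cannot decide. On X the weaker peaks were still below 1, and neither genes nor mappable sequence were counted. A lower read depth on X, which could push its sites down the ranks, stays open too, and no biological explanation was tested.

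Sites also lay somewhat more often in the centre of a chromosome, with 1909 of 4966 combined peaks (38.4%) in the middle part when each chromosome was cut into 3 equal parts. Rotation of the peaks along their chromosomes, a test chosen after that count was seen, gave one-sided permutation p = 0.0023 over 10000 rotations. Taken singly, no chromosome passed after adjustment (adjusted permutation p from 0.186 to 0.885). The share was 41.4% on V, 39.8% on I, 39.2% on III, 38.9% on II and 38.5% on IV, and 30.6% on X; the difference between X and the autosomes was not tested.

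After overlapping peaks were merged, 10.4% of the 4912 combined sites had a neighbour within 1 kb, against 10.0% with random placement on the same chromosomes (one-sided permutation p = 0.273). The densest 100 kb window was on chromosome IV from 2600001 to 2700000 with 18 sites, followed by windows with 16 sites on chromosome I from 10500001 to 10600000 and on chromosome III from 7100001 to 7200000 and from 7700001 to 7800000. The median over 999 windows was 4 sites, and 56 windows had 0.

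The combined list gave 9 intervals a second time under another peak number. One lay on chromosome III from 349396 to 350279 as peaks 478 and 1807, and another on chromosome II from 13199621 to 13200077 as peaks 236 and 3930.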
